A study of Caenorhabditis elegans with 2 samples.

How the data were processed

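The material was whole C. elegans L1 larvae of 1 strain, with ALR-1 tagged by GFP-FLAG, in 1 group of 2 biological replicates numbered as in the labels. Chromatin was sheared by sonication, per the labels. The deposited files are lists of regions, not reads or counts. Per the text files deposited with the samples, each replicate's list of peaks and background was made from that replicate's alignments and a control file, a further list from the pooled alignments, and the IDR list from those 3 lists. The build is ce11, per the labels. The aligner, the peak caller, their settings and the IDR threshold are not given in the sources used here, and the control data were not analysed here.

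Column 7 of each list holds the signal value the authors' peak caller gave to a region, relative to the control per the deposited descriptions, and it served only to rank regions within a list. The deposited -log10 q field was constant within each list (0.0464 in replicate 1, 0.0446 in replicate 2, 0.0583 in the pooled and IDR lists), so it ranked nothing and was not used. The lists had fixed widths of 344 bp in replicate 1, 384 bp in replicate 2 and 364 bp in the pooled and IDR lists. Each replicate list holds exactly 30000 regions, with lowest signals of 21.8 in replicate 1 and 23.3 in replicate 2, so absence from a list does not mean a signal of 0. Depth per sample is not known from lists of this kind, and intervals given for shares cover the counting of regions or genes only.

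Every region ended within the chromosome lengths of the reference genome, which is the same assembly under the name WBcel235. Genes came from Ensembl release 115 annotation. Summits were assigned to the first class that applied in the order promoter, 5′ UTR, 3′ UTR, coding exon, non-coding exon, intron, intergenic. Lower-ranked regions were those of the pooled list with no IDR summit within 500 bp. For gene lists, a gene had a peak when a summit lay from 1500 bp upstream to 500 bp downstream of its 5′ end. The background was the 9923 protein-coding genes, of 19973, with a pooled-list summit in that window, and genes of every biotype for the tRNA, microRNA and small RNA lists. The 32 gene lists, the rule for named genes and the tests of replicate overlap, signal correlation, promoter share, gene lists, TAATTA and chromosome X were fixed before the data were examined. The tests of other annotation classes and other chromosomes were chosen after seeing the data.

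Shared regions had summits within 200 bp, tested against 1000 circular shifts. Shares were compared by Fisher's exact test, two-sided, or an exact binomial test, with Benjamini-Hochberg adjustment over 32 lists, 7 classes, 6 chromosomes or 2080 6-mers and a threshold of 0.05. Odds ratios have Woolf 95% intervals. Motif backgrounds were 10 lower-ranked regions per peak within 1 percentage point of GC. Correlation p-values came from 100000 permutations. Named items are the 12 IDR peaks of highest signal with the genes in reach, up to 4 members with the highest peaks from each enriched, neuronal, homeobox or glia list, and alr-1, mec-3, unc-30, unc-25, mec-4, unc-119 and unc-86 in any case. Alternatives covered the distance for shared summits, the number of regions, window sizes, backgrounds, motif forms and each replicate alone. Alternatives with draws matched on GC and annotation class, permuted sums, combined lists and summits inside genes were chosen after seeing the data.

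The tests were tested on simulated data. For gene lists, random pooled-list regions were added until as many protein-coding genes had a summit as with the IDR peaks (150). With no planted gene, 3 of 100 such sets had any list called. With 6 ribosomal protein genes planted, 100 of 100 sets gave the call, and with 3 planted 19 did. With 3 pan-neuronal genes planted 21 did, and with 6 planted 100 did. With TAATTA written into 10% of sequences, 95 of 100 sets passed the threshold, and with none written in 4 did. With 40% of summits drawn from coding exons, 96 of 100 sets passed, and with 27%, the share in lower-ranked regions, 7 did. Of 80 summits planted as shared, 80 were found in 1 run. They were placed within the 200 bp limit, so this checks the matching only. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.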

Results

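Binding sites of ALR-1, a homeodomain transcription factor of the aristaless family, were mapped by ChIP-seq in Caenorhabditis elegans. The animals were whole L1 larvae of both sexes, 6 hours old and starved after bleaching, and carried an integrated alr-1 transgene with a C-terminal GFP-FLAG tag. An antibody against GFP was used for the immunoprecipitation. There was 1 group with 2 biological replicates, so the replicates can be compared with each other but no condition can be compared with another. Each replicate has a deposited list of 30000 regions ranked by signal, a mixture of peaks and background. Another list of 30000 regions came from the pooled replicates, and a final list holds 182 peaks that passed an irreproducible discovery rate (IDR) threshold. Read depth is unknown from these lists, so no value carries a sampling interval for reads. Positions are in the ce11 build, 1-based, and the signal values are the authors', comparable within a list and not between lists.

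The strongest ALR-1-GFP region lay in hsp-90, and alr-1 itself held that of rank 6. A gene was in reach when a summit lay from 1500 bp upstream to 500 bp downstream of its 5′ end. The highest of the 182 IDR peaks was on chromosome V at 14686492 to 14686855, with a pooled signal of 204. Its summit lay in a coding exon of hsp-90, which encodes the cytosolic Hsp90 chaperone, and 1189 bp upstream of C47E8.4. It ranked 1 in replicate 1 and 2 in replicate 2. The next was on chromosome I at 13653217 to 13653580 (signal 175), in an intron of rpl-31, a gene of the large ribosomal subunit, with sac-2 also in reach. The third lay in an intron of afd-1 on chromosome I (2177682 to 2178045, signal 174), ranked 26 in replicate 1 and 1 in replicate 2. The fourth was in an intron of hpo-28 on chromosome III (5707564 to 5707927, signal 162). The fifth was on chromosome III (833123 to 833486, signal 152), inside zip-2, a bZIP transcription factor gene, 323 bp downstream of its 5′ end and 130 bp upstream of the snoRNA gene K02F3.15, with ceeh-1 also in reach.

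The peak of rank 6 lay inside the alr-1 gene on chromosome X (11124016 to 11124379, signal 146), and ranked 9 in replicate 1 and 6 in replicate 2. Ranks 7 and 8 were on chromosome V. Rank 7 (18724087 to 18724450) had no protein-coding gene in reach, its nearest coding 5′ end being that of Y17D7C.2 at 4282 bp, and rank 8 (14010039 to 14010402) was in an intron of the helicase gene ddx-17. Both were high in replicate 1, at ranks 2 and 3, but stood at ranks 1050 and 495 in replicate 2. Rank 9, on X (2527212 to 2527575), was in a coding exon of tbc-12, between tRNA genes. Rank 10, on III (11505615 to 11505978), lay inside spe-6, a kinase-like gene of sperm development, 309 bp downstream of its 5′ end, with Y66D12A.21 also in reach. It stood at 401 in replicate 1 and 21 in replicate 2. Rank 11, on III (5229545 to 5229908), was in a coding exon of atp-2, which encodes the ATP synthase beta subunit, and 828 bp upstream of the arginine methyltransferase gene prmt-5. Rank 12, on IV (11344306 to 11344669), was in a coding exon of the kinesin-like gene klp-12. Of the 24 replicate ranks of these 12 peaks, 21 were within the top 182 of their list.

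The replicates shared a minority of their strongest regions. Of the 182 top regions of replicate 1, 27 had a summit within 200 bp among the 182 top regions of replicate 2, or 14.8%. Circular shifts of the replicate 2 positions gave a mean of 0.0934% and at most 1.65% (one-sided permutation test, p = 0.001, the smallest that 1000 shifts can give). Draws of 182 regions from the whole replicate 2 list, chosen after seeing the data, gave a higher mean of 0.579% and at most 3.85% (permutation p = 0.0001, the smallest that 10000 draws can give). Regions in hsp-90, rpl-31, afd-1, hpo-28, zip-2 and alr-1 were in the top 182 of both lists. In all, 26 IDR peaks were, 44 were in the top 182 of neither replicate, and 124 were in the top 1000 of both. Of the IDR peaks, 1 had no replicate 1 summit within 200 bp and 0 lacked a replicate 2 summit that close. Over the whole lists, 43.7% of replicate 1 regions had a replicate 2 summit within 200 bp, against 11.8% after shifting.

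Within the IDR peaks, signal in the replicates was inversely ordered, a direction that selection on summed signal alone also gave. Over 181 matched peaks, Spearman's rho of signal was -0.298 (permutation p = 7e-05) and Pearson's r of log10 signal was -0.212 (permutation p = 0.00436). Without the 2 peaks farthest from the median of replicate 1, r was -0.274. These values are across peaks, which are not independent replicates. The IDR peaks were exactly the 182 regions of highest signal in the pooled list, so both replicates enter their selection. The p-values above are against a correlation of 0, which such selection does not leave as the expectation. In a comparison chosen after seeing the data, replicate 2 signal was permuted among the 13046 pooled-list regions matched in both replicates before the 182 highest sums were kept. Those sets had a mean rho of -0.895 and none above -0.809. In the 182 regions of highest summed signal without permutation, the set selected in the same way, rho was -0.419 (two-sided permutation p = 0.002, the smallest that 1000 draws can give). That rho of -0.419 lay above every permuted set, so the replicates shared more order than selection on the sum alone gave. Over all 13046 regions rho was 0.203.

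**Figure D1:**
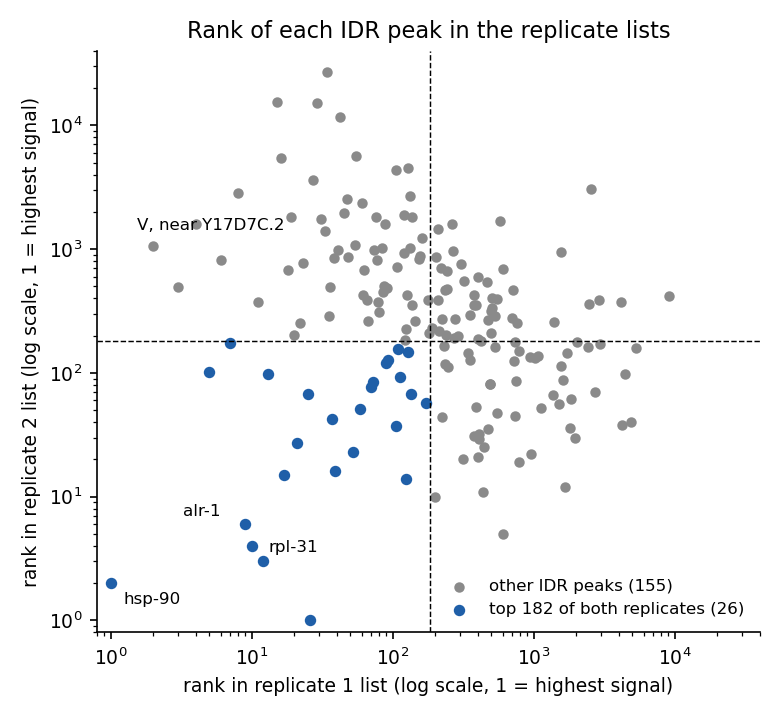
Rank of 181 IDR peaks in the list of replicate 1 (x axis) and replicate 2 (y axis), both on log scales, with dashed lines at rank 182. The 26 blue points are in the top 182 of both lists and include hsp-90, rpl-31 and alr-1, while the chromosome V peak near Y17D7C.2 ranks 2 in replicate 1 and 1050 in replicate 2.

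At alr-1 (WBGene00044330, chromosome X, 11121871 to 11125620, minus strand), several ranked regions lay in 1 gene. The pooled list had 6 summits in its 3750 bp, of which 4 were among the top 1000 regions of the genome. Of 19973 protein-coding genes, 2 held at least 4 such summits, alr-1 and the longer ssl-1. By IDR peaks alone, unc-44 (29301 bp) held 3 and alr-1, dip-2 and ssl-1 held 2 each. In each replicate's own list alr-1 held 3 of the top 1000 summits, which 8 genes including alr-1 reached in replicate 1, with up to 4 in another gene, and 4 genes including alr-1 in replicate 2. Only the summit near 11124198 was among them in both replicates. The others were 11123525 (rank 215) and 11125172 (rank 454) in replicate 1, and 11122590 (rank 30) and 11124881 (rank 140) in replicate 2. The pooled summit at 11123524 (rank 490) stood at 4530 in replicate 2. That at 11124876 (rank 695) had no replicate 1 summit within 200 bp. The 2 IDR peaks in alr-1 were that of rank 6, with its summit 1422 bp downstream of the annotated 5′ end and beside the 5′ end of the non-coding RNA gene R08B4.7, and that of rank 49 in the 3′ UTR (11122590, signal 125). The first was found in both replicates, at ranks 9 and 6. The second stood at rank 30 in replicate 2, and the nearest replicate 1 region, at 11122695, stood at rank 1954. Neither lies in the window from 1500 bp upstream to 500 bp downstream of the alr-1 5′ end, so alr-1 counts as a gene without an IDR peak in the list tests. The 20 kb on the 3′ side held 4 pooled-list regions and that on the 5′ side held 6, against a median of 5 and a 95th percentile of 10 over 885 windows of that size on X. The nearest 10 kb on the 3′ side held 0 regions in all 3 lists, as did 7.79% of 1771 windows of that size on X in the pooled list. On the 5′ side the nearest 10 kb held 4 regions in the pooled list, 5 in replicate 1 and 6 in replicate 2. The best region outside the gene and within 1500 bp upstream stood at rank 247 in the pooled list. Its counterparts stood at 370 in replicate 1 and 5230 in replicate 2.

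**Figure D2:**
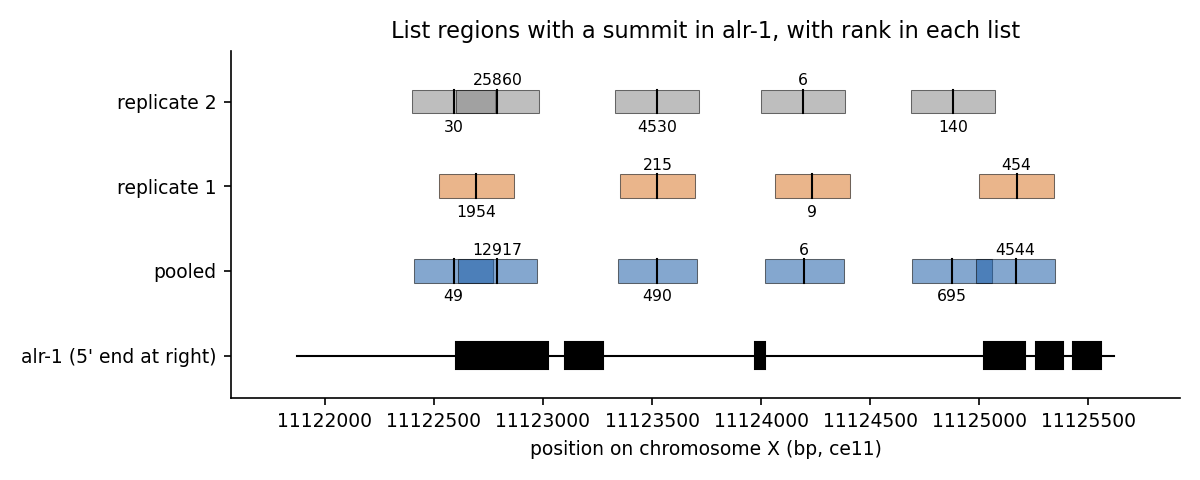
Map of alr-1 on chromosome X (position in bp, ce11) with coding exons as black boxes and every region with a summit in the gene from the pooled, replicate 1 and replicate 2 lists, drawn to its listed width. Numbers are ranks within each list, and the region near 11124198 ranks 6 in the pooled list, 9 in replicate 1 and 6 in replicate 2.

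No IDR peak lay in the window of 6 other genes chosen beforehand for neuronal roles or as the strain's marker. For mec-3, the LIM homeodomain gene of touch receptor neurons, none of the 3 lists of 30000 had a summit in the window or the gene. The best pooled-list rank inside the gene was 5803 for unc-25, which encodes glutamic acid decarboxylase, 6397 for the channel gene mec-4, 8044 for the POU homeodomain gene unc-86 and 8402 for the homeodomain gene unc-30. For unc-119, the gene mutated in this strain, it was 20244.

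IDR peaks lay more often in coding exons, and less often in introns and between genes, than lower-ranked regions of the pooled list. Of the class tests, that of promoter regions was planned and those of the other classes were chosen after seeing the data. Coding exons held 92 of 182 IDR summits (50.5%, exact 95% binomial interval 43.1 to 58.0) and 27% of 29791 lower-ranked summits, an odds ratio of 2.77 (95% interval 2.07 to 3.70; Fisher's exact test, two-sided, adjusted p = 1.57e-10 over 7 classes). By the same exact test, introns held 18.1% against 27.8% (adjusted p = 0.0082) and intergenic sequence 8.79% against 19% (adjusted p = 0.000682). The classes are shares of 1 total, so these deficits are not separate from the coding exon excess. Promoter regions, from 500 bp upstream to 100 bp downstream of an annotated 5′ end, held 36 IDR summits, or 19.8% against 20.6% (odds ratio 0.951, interval 0.66 to 1.37, Fisher's exact p = 0.854). With promoters widened to 2000 bp upstream and 200 bp downstream the shares were 65.4% and 55% (Fisher's exact p = 0.00555). Both used 5′ ends of every gene type, so the rank 6 peak inside alr-1 counted through the non-coding RNA gene R08B4.7. With protein-coding 5′ ends only, the promoter regions of 500 bp upstream to 100 bp downstream held 24 IDR summits. That was 13.2% against 10.3% (odds ratio 1.32, interval 0.858 to 2.03, Fisher's exact p = 0.22). The coding exon share was 53.3% in the 182 top regions of replicate 1 and 40.7% in those of replicate 2, each above its own lower-ranked regions. Against only the 1817 next-ranked regions of the pooled list the contrast was smaller. Coding exons held 50.5% against 38.8% there (odds ratio 1.61, interval 1.19 to 2.19, Fisher's exact p = 0.00249). The intergenic deficit was not past the threshold in replicate 2 alone, at 14.3% against 20.2% (Fisher's exact p = 0.0512).

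**Figure D3:**
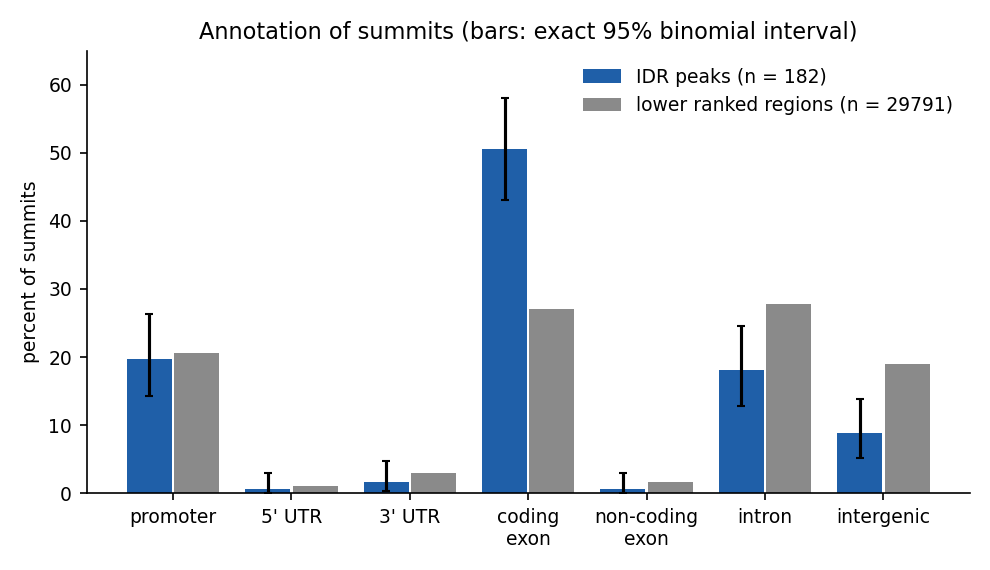
Percent of summits in each annotation class for 182 IDR peaks (blue, with exact 95% binomial intervals) and 29791 lower-ranked regions of the pooled list (grey). Coding exons hold 50.5% of IDR summits and 27% of the lower-ranked summits, and promoter regions hold 19.8% and 20.6%.

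The strongest regions were also richer in G and C. Mean GC content within 100 bp of the summit was 41.7% ± 7.9 (SD over 182 IDR peaks), against 35.7% ± 7.72 in lower-ranked regions and 35.4% in the genome. It was 42.6% in the 182 top regions of replicate 1 and 38.6% in those of replicate 2. Against lower-ranked regions matched on GC, chosen after seeing the data for this comparison, coding exons held 50.5% against 41.3% (odds ratio 1.45, interval 1.07 to 1.97, Fisher's exact p = 0.0181). The intron and intergenic shares were not compared with GC-matched regions.

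Ribosomal protein genes, and genes for small nucleolar and small nuclear RNAs, lay near IDR peaks more often than other genes. A summit fell in the window of 9 of 60 ribosomal protein genes (15%), against 1.43% of other protein-coding genes (odds ratio 12.2, interval 5.88 to 25.2; Fisher's exact test, two-sided, adjusted p = 7.95e-06 over 32 lists). The highest were rpl-31 (rank 2), rpl-7 (rank 30, summit 705 bp upstream of its 5′ end), rpl-3 (rank 37, in a coding exon) and rps-17 (rank 69, in a coding exon). The rank 30 summit lay closer to rab-11.1, 276 bp upstream of its 5′ end. In replicates 1 and 2 the peaks of rpl-31 ranked 10 and 4, of rpl-7 312 and 20, of rpl-3 52 and 23, and of rps-17 273 and 192. The snoRNA and snRNA list had 10 of 231 members with a peak (4.33%, against 0.849%; odds ratio 5.28, interval 2.76 to 10.1, Fisher's exact adjusted p = 0.000665). Its highest were K02F3.15 beside zip-2 (rank 5), R08C7.19 beside chat-1 (rank 23), Y111B2A.36 inside ssl-1 (rank 25) and F53G12.12, which shares the rank 30 peak with rpl-7. The 10 peaks behind that list include 2 that also count for ribosomal protein genes, and 8 have their summit inside a protein-coding gene. In the 182 top regions of replicate 1 alone, 4 of 63 ribosomal protein genes had a peak (odds ratio 5.45, interval 1.95 to 15.2, Fisher's exact adjusted p = 0.13), against 7 of 55 in replicate 2 alone (adjusted p = 0.000156). With a window of 500 bp upstream to 100 bp downstream, which leaves fewer genes in the background, 2 of 18 ribosomal protein genes (odds ratio 16.3, interval 3.55 to 74.8) and 2 of 102 snoRNA and snRNA genes (odds ratio 4.61, interval 1.10 to 19.3) had a peak, and neither list was past the threshold (Fisher's exact adjusted p = 0.292 and 1). In a permutation test on draws matched on GC and annotation class, chosen after seeing the data, the ribosomal protein list passed (adjusted p = 0.0064) and the snoRNA and snRNA list did not (adjusted p = 0.0992). In that test the snoRNA and snRNA list had 10 genes with a peak against a mean of 2.75 (95% of draws 0 to 7, unadjusted permutation p = 0.0062). With a summit inside the gene, also chosen after seeing the data, 7 of 50 ribosomal protein genes had a peak (odds ratio 11.7, interval 5.16 to 26.3, Fisher's exact adjusted p = 0.00021). Of snoRNA and snRNA genes 1 of 25 did (odds ratio 3.05, interval 0.410 to 22.7, Fisher's exact adjusted p = 0.845), an interval that includes the 5.28 of the main window.

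**Figure D4:**
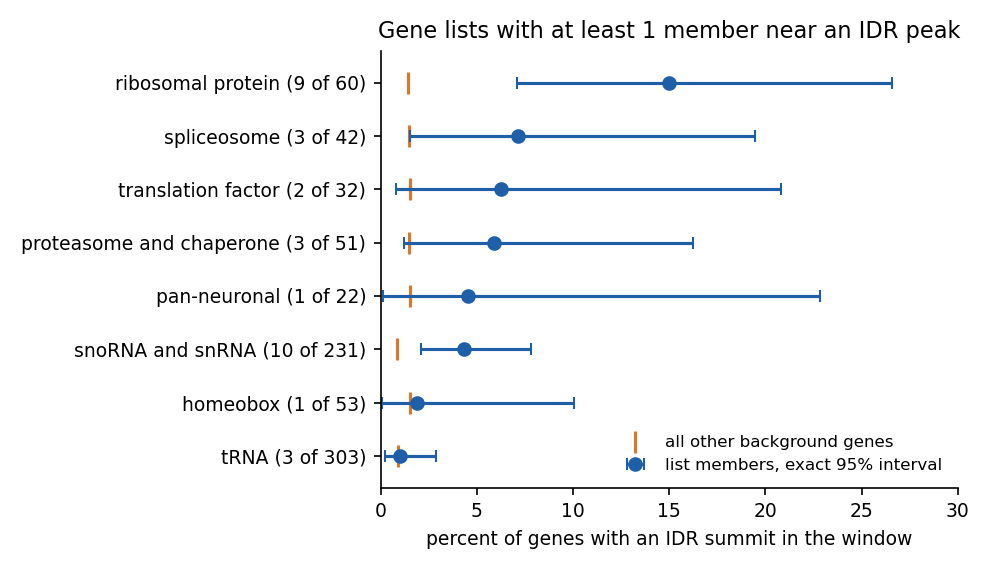
Percent of background genes with an IDR summit from 1500 bp upstream to 500 bp downstream of the 5′ end, for the 8 lists with at least 1 such gene. Blue points are list members with exact 95% binomial intervals and orange ticks are all other background genes, and ribosomal protein genes stand at 15% against 1.43%.

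No neuronal list passed the threshold. In the pan-neuronal list 1 of 22 genes had a peak (odds ratio 3.12, interval 0.416 to 23.3), unc-51, a kinase gene needed for axon growth (rank 179, summit 873 bp upstream; exact adjusted p = 1), which ranked 4922 in replicate 1 and 40 in replicate 2. In the homeobox list 1 of 53 had a peak, ceh-39 (signal 114.9, in its intron; exact adjusted p = 1), which ranked 1063 and 136. None had a peak among 6 touch receptor, 8 GABA, 8 acetylcholine, 12 glutamate and monoamine, 23 amphid chemosensory, 29 cilium, 36 neuropeptide, 26 axon guidance and 9 glia genes. Taking the 9 neuronal lists as 1 set, a choice made after seeing the data, 1 of 170 genes had a peak, or 0.588% against 1.53% of other genes (odds ratio 0.381, interval 0.0531 to 2.74, Fisher's exact p = 0.524). The direction depended on how genes were assigned. With the nearest 5′ end within 5000 bp it was 3 of 272 (unc-51, unc-44, an ankyrin gene, and eva-1; odds ratio 0.918, interval 0.291 to 2.90, Fisher's exact p = 1), and pan-neuronal genes alone had 2 of 37 (odds ratio 4.76, interval 1.13 to 19.96, Fisher's exact adjusted p = 0.579). With a summit inside the gene, chosen after seeing the data, it was 6 of 231 (odds ratio 1.86, interval 0.814 to 4.26, Fisher's exact p = 0.15), namely unc-44, egl-4, klp-11, kap-1, eva-1 and mig-10. Enrichment in the smaller lists could go undetected, since 3 of the 6 touch receptor genes would have been needed for Fisher's exact p times 32 to pass the threshold.

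Among lists of other tissues and gene families, no peak lay in the windows of 9 insulin-like peptide, 17 bHLH, 127 nuclear hormone receptor, 19 Wnt signalling, 4 heterochronic, 78 collagen, 15 epidermis, 19 body wall muscle, 12 pharynx, 17 intestine, 22 germline, 38 mitochondrial respiratory, 8 histone, 17 stress and 144 microRNA genes. For nuclear hormone receptors, the exact 95% binomial interval of 0 of 127 reaches 2.86%. Of mitochondrial respiratory genes, 3 of 39 (atp-2, cox-11 and nuo-3) had a summit inside the gene (odds ratio 5.81, interval 1.77 to 19.1, Fisher's exact adjusted p = 0.195). By Fisher's exact test, translation factors had 2 of 32 (adjusted p = 0.537), spliceosome genes 3 of 42 (adjusted p = 0.27), proteasome and chaperone genes 3 of 51 (adjusted p = 0.333) and tRNA genes 3 of 303 (adjusted p = 1).

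The TAATTA core that paired-class homeodomains bind was not more frequent at IDR summits. It occurred within 100 bp of 14 of 182 summits (7.69%, exact 95% binomial interval 4.27 to 12.57) and of 8.19% of 1820 GC-matched lower-ranked summits (odds ratio 0.935, interval 0.528 to 1.65; Fisher's exact test, two-sided, p = 1). The peaks in alr-1 (rank 6) and hpo-28 (rank 4) had it, and those in hsp-90, rpl-31, afd-1 and zip-2 did not. Of 2080 6-mers counted on both strands, TAATTA ranked 1156 by odds ratio, and none passed the threshold after adjustment, with 115 at an unadjusted p under 0.05. The dimer TAATNNNATTA occurred at 1 IDR summit. Within 200 bp of the summit the shares with TAATTA were 17.6% and 11.5% (odds ratio 1.64, Fisher's exact p = 0.0228, not adjusted for the settings tried).

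**Figure D5:**
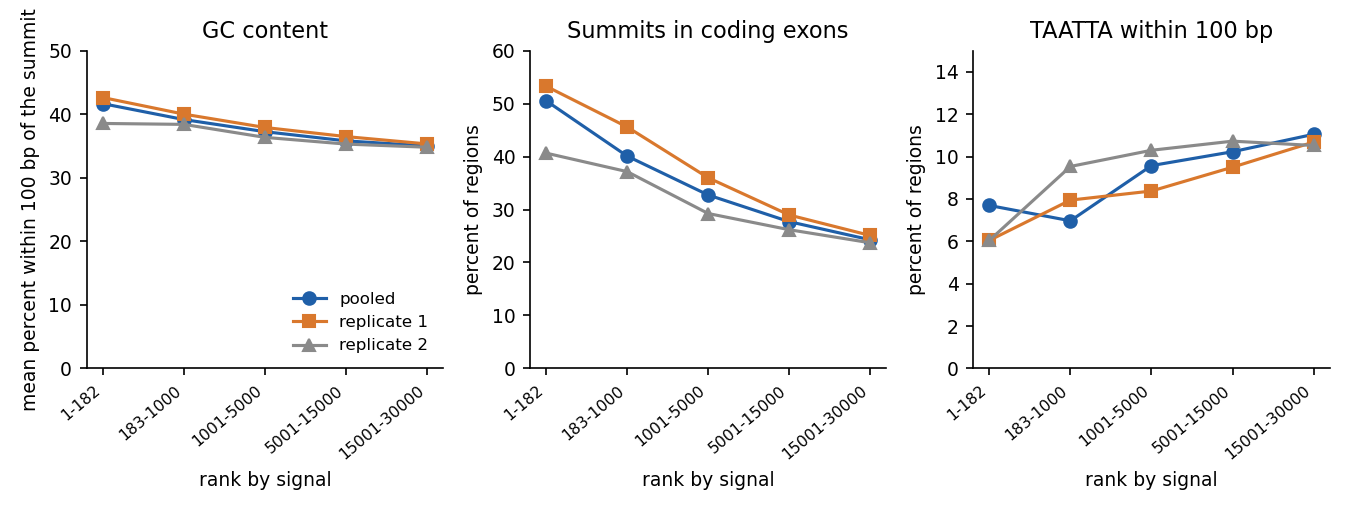
Mean GC content, percent of summits in coding exons and percent of regions with TAATTA within 100 bp, by rank of signal in the pooled, replicate 1 and replicate 2 lists of 30000 regions each. GC content in the pooled list goes from 41.7% in ranks 1 to 182 to 35% in ranks 15001 to 30000, and coding exons go from 50.5% to 24.3%.

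IDR peaks were scarce on chromosome X and frequent on chromosome III. X held 13 of 182 (7.14%, exact 95% binomial interval 3.86 to 11.9), against 16.6% of the pooled list (exact binomial test, two-sided, p = 0.000212). Chromosome III held 52 (28.6%, interval 22.1 to 35.7) against 15.3%, a contrast chosen after seeing the data (exact binomial p = 4.4e-06, adjusted p = 2.64e-05 over 6 chromosomes). X held 6.04% of the 182 top regions of replicate 1 and 9.89% of those of replicate 2, and III held 29.1% and 23.6%. Below the IDR peaks the pooled X share was 10.3% in ranks 183 to 1000 and 13.6% in ranks 1001 to 5000. It reached 18% in ranks 15001 to 30000, where X held 17.3% in replicate 1 and 18.4% in replicate 2. The low X share was thus not confined to the IDR peaks but changed gradually with rank, a trend that was not tested. The share of III was not compared by rank. The remaining shares were 20.9% on I, 8.24% on II, 22% on IV and 13.2% on V, none past the threshold after adjustment. In draws of lower-ranked regions matched on GC and annotation class, also added after seeing the data, X held a mean of 13.9% (95% of draws 9.34 to 19.2) and III 17.2% (12.1 to 22.5).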

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

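The alternatives with draws, GC matching, permuted sums or summits inside the gene, those that leave out the alr-1 peaks, and every test, with its alternatives, on coding exons, introns, intergenic sequence and chromosome III were chosen after seeing the data. The replicate overlap, the coding exon excess, the X deficit and the chromosome III excess kept their direction and their side of the threshold under every alternative run, the overlap ranging from 13.2% to 20.8%. The coding exon odds ratio fell from 2.77 to 1.61 against the next-ranked regions and to 1.45 against GC-matched regions. Taking the 182 top pooled regions in place of the IDR peaks changes nothing, because they are the same regions. The promoter odds ratio turned above 1 with a 2000 bp window (1.55), with protein-coding 5′ ends only (1.32) and against the next-ranked regions (1.05), and only the first passed the threshold; the cause was not tested. The TAATTA odds ratio turned above 1 within 50 bp (1.40), within 200 bp (1.64, past the threshold), against the next-ranked regions (1.17) and in replicate 1 alone (1.08); the cause was not tested. It was 0.797 to 1.08 over each replicate alone. The rho of replicate signals lay 0.597 above that of permuted signals selected on their sum, and 0.476 above it in the regions selected in the same way. The intergenic odds ratio was 0.155 to 0.66 over each replicate alone, past the threshold without replicate 2 and not without replicate 1; the cause was not tested. The 2 enriched lists became 1 to 2 over each replicate alone, 0 with the 500 bp window, which leaves 18 ribosomal protein genes in the background, 1 with draws matched on GC and annotation class, and 1 with summits inside the gene, which leaves 25 snoRNA and snRNA genes in the background. Of the 10 named genes with a peak, 9 lost it with the 500 bp window, and they kept it in 22 of 40 comparisons over the alternatives. The 7 named genes without a peak gained none in 28 comparisons. Depth limits all of these to an unknown extent.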

Other observations

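The tests on coding exons, with and without GC matching, on the combined housekeeping lists, on genes with a summit inside them, and on the flanks of alr-1 were chosen after their values had been seen, as was setting the planned TAATTA share against the coding exon excess. Peaks also lay near members of the spliceosome, translation factor, and proteasome and chaperone lists, named after their values were seen. The splicing genes rsp-6 (rank 18), snr-7 (rank 46) and snr-2 (rank 116), the translation factor genes eif-3.D (rank 17) and eif-6 (rank 133), and the protein-folding and degradation genes dnj-1 (rank 108), pbs-2 (rank 133) and cct-7 (rank 139) each had a summit in their window. The summit near eif-6 and pbs-2 is the same peak, which lay inside pbs-2 and 789 bp upstream of eif-6. The summits counted for rsp-6, snr-7, snr-2 and cct-7 lay 534, 612, 788 and 1315 bp upstream of their 5′ ends. These summits were inside other genes, namely C33H5.13, Y71F9B.6, W08E3.4 and T10B5.4.

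The 26 IDR peaks within the top 182 of both replicates had 14 summits in coding exons, 6 in introns and 6 in promoter regions, with none between genes. Their hosts include ttb-1, egl-4, aakg-1, prp-8, eor-1 and dip-2, also chosen after their values were seen. TAATTA lay within 100 bp of 3 of them, in hpo-28, alr-1 and clec-80, or 11.5%. The share was 8.19% in the regions GC-matched to all 182 IDR peaks (odds ratio 1.46, interval 0.434 to 4.93, Fisher's exact test, p = 0.468). Mean GC content was 42.8% at the 26 peaks and 41.6% in those regions, which were not matched to the 26 alone.

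Coding exons held more IDR summits than lower-ranked summits, with an odds ratio of 2.77. GC content may account for part of this, but against GC-matched regions the odds ratio was still 1.45 (interval 1.07 to 1.97), which argues against GC as the whole source. Binding at the TAATTA core is unlikely to account for most peaks, since 7.69% had it within 100 bp, with an upper 95% bound of 12.57%. Within 200 bp 17.6% had it, with an upper bound of 23.9%, against 11.5% of GC-matched regions (odds ratio 1.64, Fisher's exact p = 0.0228). Of 2080 6-mers, 0 passed the threshold after adjustment, and recruitment through partner proteins was not tested.

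Ribosomal protein genes had peaks in 9 cases, where draws of lower-ranked regions matched on GC content and coding position gave a mean of 1.09 (95% of draws 0 to 3.02), which argues against those properties as the whole source. In replicate 1 alone 4 genes had a peak (odds ratio 5.45, interval 1.95 to 15.2) and the list was not called. A candidate explanation is signal at housekeeping genes irrespective of the tagged protein. In 4 other housekeeping lists 8 of 163 genes had a peak (odds ratio 3.71, interval 1.79 to 7.71), but the lists were combined after 3 of them had shown odds ratios above 4, the mitochondrial respiratory list had 0 of 38 in the window but 3 of 39 with a summit inside the gene (odds ratio 5.81, interval 1.77 to 19.1), and none passed in draws matched on GC and annotation class (lowest permutation p = 0.0632, adjusted p = 0.618). With the top regions of each replicate alone, the combined lists had 5 of 163 in replicate 1 (odds ratio 2.66, interval 1.07 to 6.61). In replicate 2 they had 7 of 163 (odds ratio 4.02, interval 1.84 to 8.78). The odds ratios of the combined lists all used the pooled-list background, with 9700 other genes that leave out ribosomal protein genes. The ribosomal protein count for replicate 1 alone used the background of that replicate's own list. Signal at housekeeping genes and binding by ALR-1 cannot be told apart without an immunoprecipitation from untagged animals, not analysed here.

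The cluster at alr-1 has 4 of the top 1000 pooled summits in 1 gene, as many as the longer ssl-1 on chromosome III, and 2 IDR peaks, against 3 in the longer unc-44. Of these 4 summits at alr-1, only that at 11124198 had a counterpart in the top 1000 of both replicates. Extra copies of the tagged transgene could raise signal there, and the flanks do not decide it: the 20 kb on the 3′ side held 4 pooled-list regions and the 5′ side 6, neither above the 95th percentile of 10, but the extent of the transgene is not given in the sources used here. The nearest 10 kb on the 3′ side held 0 regions in all 3 lists, which 7.79% of such windows on X also did in the pooled list. Binding at TAATTA in alr-1 could also give the cluster, since 50% of these 4 summits had the core, but 4 summits are too few (exact 95% interval 6.76 to 93.2, against 10.5% of lower-ranked regions). Of the 2 with the core, that at 11124876 had no replicate 1 summit within 200 bp. The transgene and binding cannot be told apart here.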
